A study of Mus musculus with 12 samples.

How the data were processed

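RNA sequencing libraries from the ventricles of 12 wild-type mice were analysed, 4 each from the saline, AngII and AngII_FI groups, taken from the treatment label of each sample. Per the labels' protocols, the RNA was taken with TRIzol in one field and with an RNeasy kit in another, which differ, and 1.3 µg entered a SMARTER mRNA library kit. The authors deposited a table of raw counts per gene with 1 column per library. Per the submitters' processing notes, HISAT, featureCounts 1.5.0-p3 and DESeq 1.8.3 were used with build GRCm38. The strand setting, the treatment of reads that map to several places and the annotation release are not given in the sources used here, so genes that overlap, and nuclear copies of mitochondrial genes, are uncertain. Of whole values between 1 and 40, 33.9% to 36.6% per library were multiples of 4, against 25% by chance, and the reason is not known.

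The table held 55421 genes, of which 27438 had no count in any library, and 13 unnamed empty columns. Date-like symbols of 27 genes were repaired by gene ID. Coordinates, biotypes and overlaps came from GENCODE M21 (GRCm38) and matched 55240 IDs, or 99.7%. Total counts were 68874852 to 80624227 per library, so a count of 3 equals 0.0372 to 0.0436 CPM; such floors cover counting error only. Genes were filtered by edgeR's filterByExpr, scaled by TMM and tested with the quasi-likelihood test (edgeR 4.0.16, R 4.3.3) in 1 fit of all 12 libraries with 3 group means and no covariates, and p-values were adjusted by the Benjamini-Hochberg method over 17376 genes. Values are CPM with the SD over 4 libraries, and log2 fold changes carry standard errors.

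Gene lists (41, each with 3 or more tested members) were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation and with fry. Lists of hepatocyte markers were added after the libraries had been examined. The lists and a rule for the genes named were set before the data were examined. The rule takes the 10 largest increases and decreases among called protein-coding genes with a mean of at least 1 CPM and no overlap between the groups, or, where none pass, the 5 smallest p in each direction. It also takes up to 4 members by p of each list that passed, and a fixed set of cardiac, matrix and inflammatory genes. Only the first 2 members by p of each list are described, a limit set after the values were seen. Some genes that the rule takes are not reported here, and no others took their place. Other settings chosen in advance were DESeq2 1.42.0, limma-voom, other scalings, filters, designs and fold thresholds, and each library left out in turn. Leaving out both libraries with hepatocyte transcripts, summing overlapping models, leaving out mitochondrial genes and splitting the saline libraries between the comparisons were chosen after seeing the data.

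Library measures and list scores were compared with exact two-sided permutation tests in Python 3.11, which cannot go below p = 0.0286 with 4 against 4, on mean log2 values of CPM plus 0.05 for the scores. The procedure was tested on simulated counts with known changes. For AngII against saline, 6 of 64 genes changed 1.5-fold, 43 of 69 changed 2-fold and 59 of 67 changed 4-fold were recovered among 16968 genes; for AngII_FI against AngII these were 10 of 60, 41 of 71 and 63 of 69 among 16960 genes. Of the calls in these simulations, 2.70% and 1.72% were of unchanged genes.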

Results

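Gene expression was measured by RNA sequencing in the ventricles of wild-type mice in 3 groups of 4 libraries. The saline group received saline and vehicle. The AngII group received angiotensin II, a peptide hormone that raises blood pressure and drives cardiac remodelling, from an osmotic minipump, together with vehicle. The AngII_FI group received angiotensin II and Forsythoside I (FI), given by intraperitoneal injection at 50 mg/kg every other day, starting the day before the pump was implanted and ending on day 14. No group received saline with FI, so an effect of FI in the absence of angiotensin II was not measured. The 12 libraries held 68874852 to 80624227 counts each, of which 29.1% to 38.8% fell on mitochondrially encoded genes, and 17376 of the 55421 listed genes were tested.

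One library stood apart. AngII_FI 3 held 30945 CPM (counts scaled to the library total) on 25 hepatocyte markers, or 3.09% of its counts, against 27.9 to 43.9 CPM in the other libraries except AngII 3, which held 95.6 CPM. Xist, transcribed from the inactive X chromosome of females, had 12419 counts in AngII_FI 3 and 0 to 14 in the others, while the Y-linked genes of AngII_FI 3 lay at 0.807 times the median of the others. The median Spearman correlation across genes of AngII_FI 3 with the other libraries was 0.936, against 0.976 to 0.981 for the rest, and the component that set it apart carried 40.1% of the variance of the 500 most variable genes. The common biological coefficient of variation was 0.343 with this library and 0.269 without it.

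**Figure D1:**
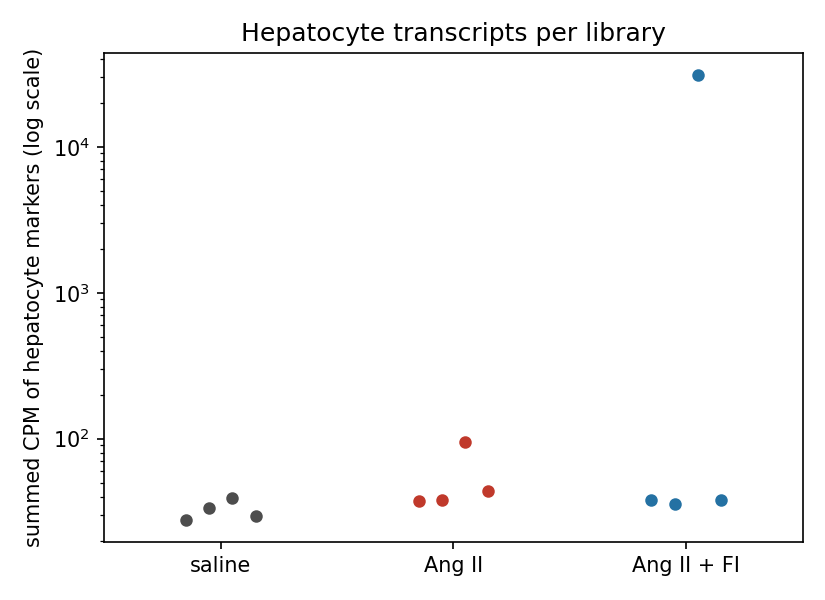
Summed CPM of 25 hepatocyte markers (log axis) in each of the 12 libraries, 1 point per library, by group. AngII_FI 3 lies at 30945 CPM, AngII 3 at 95.6 CPM and the other libraries between 27.9 and 43.9 CPM.

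The comparison of AngII with saline asks which ventricular transcripts change under angiotensin II. Most matrix genes and part of the stress genes of the cardiomyocyte rose. Of 31 tested collagens and matrix proteins, 24 rose and 0 fell (27 adjusted over the list alone), with a median log2 fold change of 0.87. Col1a1, a chain of type I collagen (chromosome 11, 94936224 to 94953042), went from 40.03 ± 5.29 to 79.2 ± 5.98 CPM (mean ± SD, n = 4 per group), a log2 fold change of 0.98 ± 0.10 (SE, edgeR adjusted p = 8.58e-04). Nppa, which encodes atrial natriuretic peptide (chromosome 4, 148000722 to 148002079), went from 111 ± 17.1 to 302 ± 27.5 CPM. For both genes the 4 AngII values lay above the 4 saline values, as did one group above the other for 13.5% of all tested genes, where chance gives 2.86%. Across all genes, 273 were higher and 115 lower with angiotensin II by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, and 2915 had an unadjusted p under 0.05, where chance gives 869.

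Within the matrix list, Col16a1 rose by 1.03 ± 0.11 on the log2 scale and Ltbp2, a latent TGF-beta binding protein of microfibrils, by 2.11 ± 0.22 (edgeR adjusted p = 8.09e-04 and 8.09e-04). Col3a1, whose gene model overlaps another on the same strand, rose by 0.98 ± 0.16. Of 23 genes for matrix cross-linking and turnover, 7 rose, among them Loxl1, a lysyl oxidase (0.92 ± 0.12), and Mmp2, a gelatinase (0.80 ± 0.10). Of 23 markers of activated fibroblasts and the TGF-beta response, 11 rose. Cilp rose by 1.92 ± 0.15 on the log2 scale, Postn, the matricellular protein periostin (chromosome 3, 54361109 to 54391037), from 34.1 ± 6.44 to 119 ± 9.81 CPM (1.798 ± 0.16 on the log2 scale), Ccn2, the connective tissue growth factor, by 1.20 ± 0.11 and Tgfb1 by 0.64 ± 0.14. Of 14 resting fibroblast markers, 2 rose, Pi16 by 1.01 ± 0.14 and Cd34 by 0.61 ± 0.12 (list adjusted p = 0.275 with an estimated correlation and 0.0226 by fry). Markers of other cells were higher as well, the mean log2 CPM differing by 0.66 for macrophage markers, 0.34 for resting fibroblast markers and 0.25 for pericyte and smooth muscle markers (exact two-sided permutation p = 0.0286 and adjusted p = 0.0482 for each) and by 0.24 for endothelial markers (p = 0.171). Endothelial and pericyte lists had medians of 0.29 and 0.20, with 0 of 13 and 1 of 13 members past the threshold, and the adult contractile and calcium-handling genes of -0.22, with 18 of 22 below 0 and 0 past it. These 3 lists were called by camera with the preset correlation and not with an estimated one (adjusted p = 0.471, 0.345 and 0.360) or by fry (0.188, 0.0697 and 0.120). Each of the 12 libraries was left out in turn, and the lost calls are given with the range of log2 fold changes over the 12 fits. Col3a1 lost its call in 1 (without AngII 4, 0.86 to 1.10), Tgfb1 in 8 (0.56 to 0.75) and Cd34 in 7 (0.49 to 0.67).

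Of 14 fetal and stress genes of the cardiomyocyte, 4 rose, including Nppa by 1.44 ± 0.13 and Nppb, which encodes brain natriuretic peptide (chromosome 4, 147985788 to 147987205), by 1.47 ± 0.23 on the log2 scale. Acta1, the skeletal alpha-actin, rose by 1.67 ± 0.32 (edgeR adjusted p = 0.0228). Myh7 had a log2 fold change of 0.09 ± 0.21, Myh6 of -0.18 ± 0.17 and Atp2a2, the sarcoplasmic calcium pump, of -0.45 ± 0.12, none past the threshold (edgeR adjusted p = 0.890, 0.685 and 0.0833). Fatty acid oxidation genes had a median of -0.25, and 4 of 29 fell, among them Hadh (-0.37 ± 0.06) and Hadhb (-0.43 ± 0.08), enzymes of mitochondrial beta-oxidation. Of 19 genes of the TCA cycle and pyruvate dehydrogenase, 1 fell, Idh3g (-0.40 ± 0.09). The adjusted p with an estimated correlation was 0.261 for fatty acid oxidation and 0.275 for the TCA cycle, and by fry 0.0196 and 0.0277. Acta1 lost its call in 5 (1.46 to 1.98), Hadh in 4 (-0.40 to -0.34) and Hadhb in 4 (-0.47 to -0.40). Idh3g lost its call in 9 (-0.44 to -0.34).

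Among immune genes, 6 of 18 macrophage markers rose, including the complement genes C1qb (0.76 ± 0.12) and C1qc (0.60 ± 0.10), as did 4 of 10 resident macrophage markers, including Mrc1 (0.42 ± 0.08) and Lyve1 (0.72 ± 0.15). For these lists the adjusted p with an estimated correlation was 0.0962 and 0.117, and by fry 0.00178 and 0.00283. Trem2 rose by 0.99 ± 0.20, and the NADPH oxidase subunits Ncf4 and Rac2 by 0.98 ± 0.16 and 0.70 ± 0.13. Of 28 inflammatory genes, 2 rose, Ptgs2 (1.53 ± 0.30) and Tlr4 (0.64 ± 0.15), and the list had an adjusted p of 0.157 with an estimated correlation and 0.0196 by fry. Il1b, Il6, Tnf, Ccl2 and Nlrp3 did not pass the threshold, with log2 fold changes of 0.56 ± 0.28, 2.90 ± 0.98, -0.40 ± 0.59, 0.06 ± 0.41 and 0.52 ± 0.65. Nor did Agtr1a, the type 1 angiotensin receptor (-0.58 ± 0.19), Hmox1 (0.66 ± 0.17) or Nqo1 (0.04 ± 0.11). Il6 averaged under 1 CPM in AngII and less in saline, so its log2 fold change rests on few counts. The glucocorticoid targets Mt2 and Fkbp5 rose by 1.65 ± 0.38 and 1.32 ± 0.31 (list adjusted p = 0.275 with an estimated correlation and 0.0632 by fry). The cell cycle list had a median of 0.69, yet its only member past the threshold, Cenpf, a kinetochore protein, was lower (-0.82 ± 0.18). The adjusted p of that list was 0.267 with an estimated correlation and 0.0371 by fry. C1qc lost its call in 1 (without saline 4, 0.51 to 0.64), Mrc1 in 7 (0.35 to 0.45) and Lyve1 in 6 (0.62 to 0.83). Trem2 lost its call in 7 (0.92 to 1.10), Rac2 in 2 (without saline 4 and AngII 2, 0.63 to 0.75) and Ptgs2 in 5 (1.37 to 1.72). Tlr4 lost its call in 10 (0.52 to 0.70), Mt2 in 11 (1.11 to 1.84) and Fkbp5 in 10 (1.16 to 1.60). Cenpf lost its call in 6 (-0.90 to -0.73).

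Among called protein-coding genes with a mean of at least 1 CPM and no overlap between the groups, the largest increases included, after Etfbl, those of Tceal7 (4.42 ± 0.81), Col12a1 (2.86 ± 0.48), Wnt9b (2.46 ± 0.43), Pthlh (2.25 ± 0.38), Ltbp2, Mybpc2 (2.01 ± 0.19), Fgf6 (2.01 ± 0.45) and Edn3 (2.00 ± 0.34). Etfbl had no count in any saline library and 1.29 CPM in AngII, at least 120-fold above a floor of 3 counts over the group, but its gene model overlaps another on the same strand, and with overlapping models summed the log2 fold change was -0.20. The largest decreases were those of Snai3 (-1.40 ± 0.30), Stum (-1.26 ± 0.25), Syt3 (-1.25 ± 0.29), Slc22a3 (-1.19 ± 0.24), Grhl2 (-1.17 ± 0.26), Sbk2 (-1.15 ± 0.24), Ky (-1.09 ± 0.20), Cngb3 (-1.08 ± 0.15), Ccl11 (-1.04 ± 0.23) and Ncoa1 (-1.01 ± 0.17). Etfbl lost its call in 7, Tceal7 in 3 (4.00 to 5.41) and Col12a1 in 1 (without saline 4, 2.73 to 3.24). Wnt9b lost its call in 3 (2.17 to 2.65), Pthlh in 2 (without saline 1 and saline 4, 2.03 to 2.68) and Fgf6 in 11 (1.74 to 2.36). Edn3 lost its call in 1 (without saline 4, 1.67 to 2.15), Snai3 in 8 (-1.66 to -1.26) and Stum in 6 (-1.40 to -1.15). Syt3 lost its call in 9 (-1.44 to -1.08), Slc22a3 in 6 (-1.38 to -1.01) and Grhl2 in 9 (-1.42 to -1.04). Sbk2 lost its call in 7 (-1.25 to -1.02), Ky in 5 (-1.25 to -0.98) and Ccl11 in 8 (-1.15 to -0.93). Ncoa1 lost its call in 2 (without saline 4 and AngII 2, -1.19 to -0.88). Tceal7 had 0 to 14 counts in the saline libraries and 100 to 143 in the AngII libraries. It is among 98 genes, of a mean of at least 1 CPM, that differed 20-fold or more between the 11 libraries without AngII_FI 3. That range was taken across all groups. One AngII library lay far from the others of its group for Mmp2, Mt2, Edn3, Pthlh and Eln.

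Of 41 fixed gene lists, 19 were higher and 5 lower with angiotensin II by camera with a preset correlation of 0.01, and 3 of the 35 splits of these libraries called as many lists. With an estimated correlation 5 held: the collagens (adjusted p = 0.0275), activated fibroblast markers (0.0217), matrix cross-linking (0.0386), fetal and stress genes (0.0275) and NADPH oxidase subunits (0.0467). The adjusted p for recruited macrophages was 0.176 with an estimated correlation and 0.0196 by fry, which called 15 of the 41 lists. The gene counts moved with single libraries. AngII_FI libraries enter this comparison only through the filter, the scaling and the spread shared by the groups. The common biological coefficient of variation was 0.343 with AngII_FI 3 and 0.269 without it. Higher and lower genes numbered 106 and 19 without saline 1, 156 and 41 without saline 2, 238 and 69 without saline 3, 79 and 11 without saline 4, 98 and 14 without AngII 2, 109 and 20 without AngII 3, 80 and 15 without AngII 4, 441 and 242 without AngII_FI 3 and 207 and 64 without AngII_FI 4.

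**Figure D2:**
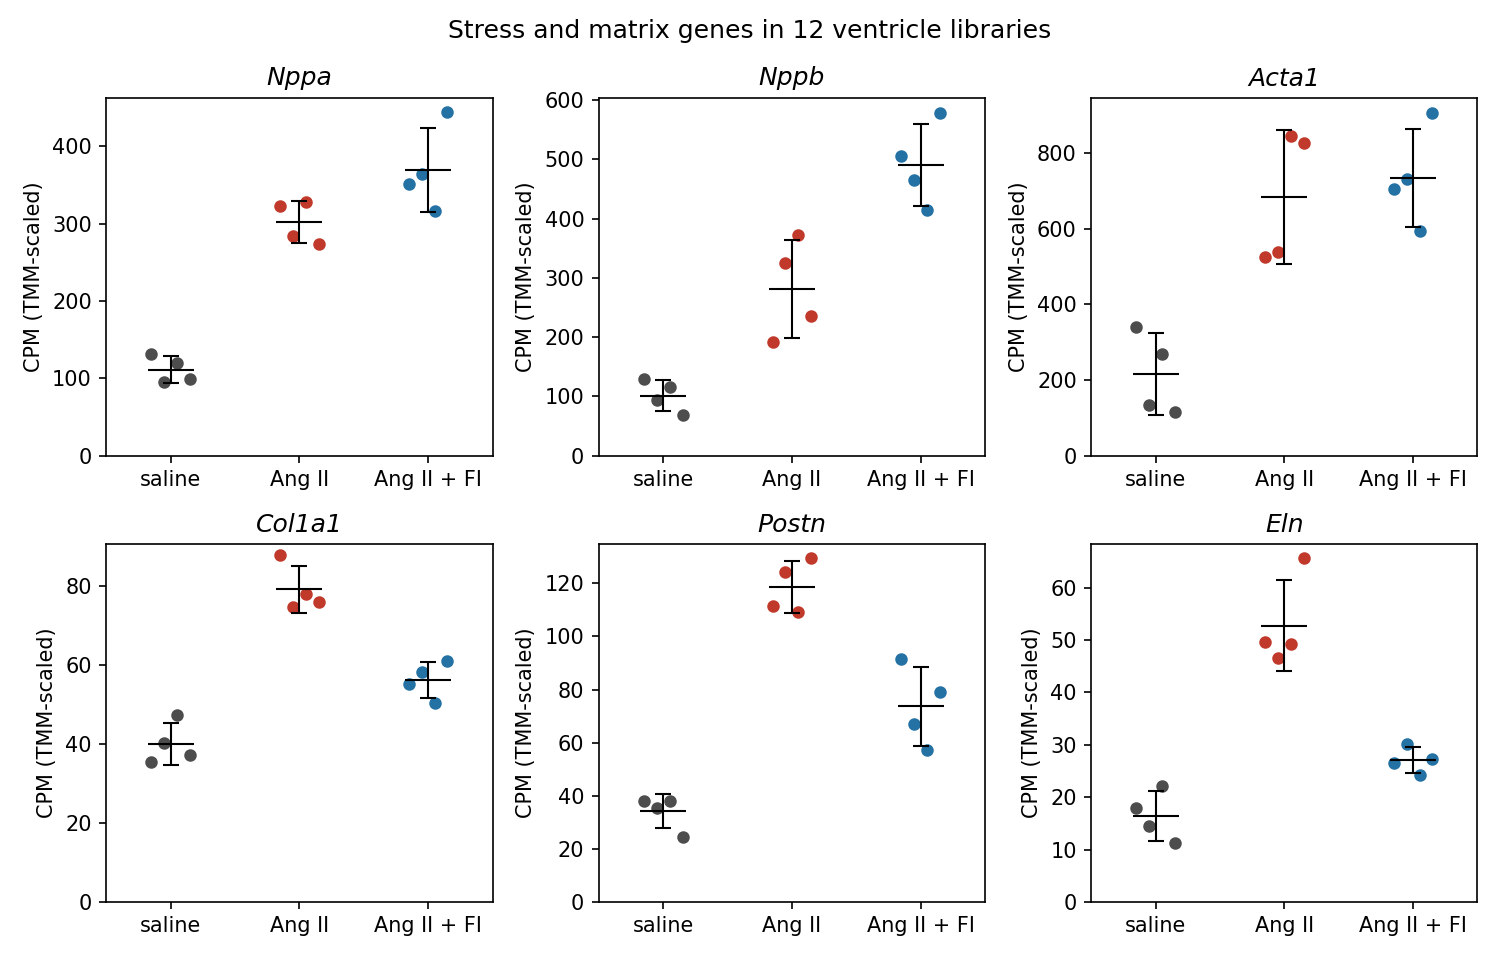
CPM (TMM-scaled, linear axis from 0) of 6 genes in the 12 libraries, 1 point per library, with the group mean and SD as bars. Nppa, Nppb and Acta1 are higher in both angiotensin II groups than in saline, and the AngII_FI means of Col1a1, Postn and Eln lie between those of saline and AngII.

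The comparison of AngII_FI with AngII asks what FI changes under angiotensin II. Matrix genes were lower on balance with FI by camera with the preset correlation (adjusted p = 1.13e-16), but not with an estimated correlation (adjusted p = 0.289) or by fry (adjusted p = 0.0554). For single genes, edgeR's quasi-likelihood test called 0 higher and 0 lower with FI, with 1729 at an unadjusted p under 0.05, where chance gives 869, while DESeq2 called 12 higher and 30 lower and limma-voom 0 of either. With 1 library left out, the 1729 became 1247 (without AngII 2) to 2328 (without AngII_FI 1). How far that number varies by chance was not measured. The 31 collagens and matrix proteins had a median log2 fold change of -0.45 (-0.42 without AngII_FI 3), with 29 below 0, 0 past the threshold over all genes and 17 lower adjusted over the list alone. Their mean log2 CPM was 4.84 ± 0.12 in AngII_FI and 5.25 ± 0.11 in AngII (SD, n = 4 per group, exact two-sided permutation p = 0.0286, the smallest this design allows, adjusted p = 0.0482 over 27 such tests), against 4.16 ± 0.20 in saline. Markers of other cells lay lower as well, the mean log2 CPM differing by -0.32 for endothelial markers (exact two-sided permutation p = 0.0571), -0.21 for pericyte and smooth muscle markers (0.143), -0.15 for resting fibroblast markers (0.0286) and -0.15 for macrophage markers (0.229). Without AngII_FI 3 the difference was -0.33 for pericyte and smooth muscle markers (exact two-sided permutation p = 0.0286) and -0.0862 for macrophage markers (0.400). Eln, which encodes elastin (chromosome 5, 134702593 to 134747323), went from 52.7 ± 8.67 to 27.1 ± 2.44 CPM, a log2 fold change of -0.96 ± 0.18, and Col1a1 from 79.2 ± 5.98 to 56.3 ± 4.58 CPM (-0.49 ± 0.10). The edgeR adjusted p was 0.411 for both, which was also the smallest of any gene.

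Of all tested genes, 5.40% had no overlap between the groups, where chance gives 2.86%. The genes with the smallest p by edgeR, none of which passed its threshold, were Zbtb42 (2.65 ± 0.49), Josd2 (0.33 ± 0.07), Gm19410 (0.93 ± 0.21), Actr1a (0.48 ± 0.11) and Rnf181 (0.84 ± 0.19) among the higher and Eln, Adamts9 (-0.88 ± 0.17), Spsb1 (-0.50 ± 0.10), S1pr1 (-0.64 ± 0.13) and Ctla2b (-0.65 ± 0.13) among the lower. Zbtb42 is also among the 98 genes that differed 20-fold or more, with 14 to 68 counts in AngII, 271 to 303 with FI and 64 to 285 in saline. Leaving out AngII 2 gave 1 higher gene, and leaving out AngII 1, AngII_FI 1 or AngII_FI 3 gave 1 lower gene each.

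The fibroblast genes Postn, Cilp and Col3a1 had log2 fold changes of -0.69 ± 0.16, -0.56 ± 0.14 and -0.73 ± 0.16 with FI and Ccn2, of the same list as Postn and Cilp, of 0.11 ± 0.11. Matrix cross-linking genes had a list median of -0.22 (adjusted p = 0.289 with an estimated correlation). The fetal and stress genes went both ways, with 9 of 14 above 0 and 5 below, a median of 0.11, a mean of -0.11 and a camera adjusted p of 0.467. Nppb was at 0.80 ± 0.22, Nppa at 0.29 ± 0.13, Acta1 at 0.10 ± 0.31 and Myh7 at 0.36 ± 0.21, and Myh6, which is not on that list, at 0.33 ± 0.18, none past the threshold. Whether these genes differ in direction from the matrix genes was not tested. Endothelial markers had a median of -0.32, with Pecam1 at -0.57 ± 0.15 and Kdr, a VEGF receptor, at -0.41 ± 0.15 (list adjusted p = 0.511 with an estimated correlation). Tagln, a smooth muscle gene, was at -0.52 ± 0.14 and Cdkn1a, the cell cycle inhibitor p21, at -0.87 ± 0.21. The circadian clock list had a median of 0.27, with Nr1d1 at 0.73 ± 0.18 and Bhlhe41 at 0.63 ± 0.15 (list adjusted p = 0.503 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.12 (0.18 without AngII_FI 3) and red blood cell markers of 0.72 (adjusted p = 0.623 and 0.614 with an estimated correlation).

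The cytokine and receptor genes Il1b (-0.16 ± 0.28), Tnf (-0.64 ± 0.60), Ccl2 (0.08 ± 0.41), Nlrp3 (-1.24 ± 0.66), Tgfb1 (-0.32 ± 0.14) and Agtr1a (0.22 ± 0.18) did not pass the threshold, nor did Nqo1 (0.10 ± 0.11), Hmox1 (0.11 ± 0.17) or Atp2a2 (0.15 ± 0.12). Il6 did not pass either, at 0.279 ± 0.158 CPM in AngII and 0.139 ± 0.0629 CPM with FI. Some values moved with AngII_FI 3, the library with hepatocyte transcripts. The log2 fold changes of Trp53inp1 (1.92 ± 0.75) and Gdf15 (2.39 ± 1.06) were -0.04 and -0.65 without that library, and the median of the NRF2 target list went from 0.18 to 0.10, that of adipocyte markers from 3.64 to -1.13. By camera with the preset correlation, 10 lists were higher and 9 lower. Higher and lower lists numbered 4 and 8 without AngII 1, 4 and 10 without AngII 2, 5 and 8 without AngII_FI 2 and 5 and 9 without AngII_FI 4. None held with an estimated correlation, where the smallest adjusted p was 0.289, or by fry, where it was 0.0554. The adjusted p with an estimated correlation was 0.289 for the pericyte list and 0.614 for NRF2 targets.

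Log2 fold changes for AngII against saline and for AngII_FI against AngII correlated at r = -0.187 across genes, which are not independent replicates, with a covariance of -0.0738. Both comparisons use the AngII libraries. Over 25 simulations of an FI group that did not differ from AngII, r averaged -0.337 (range -0.361 to -0.288) and the covariance -0.0981 (-0.106 to -0.0815), so the observed covariance lay 0.0242 above the simulated mean and above that range. Without AngII_FI 3 the observed r was -0.348 against a simulated -0.293 (-0.338 to -0.260). The covariance was then -0.122 against -0.0993 (-0.118 to -0.0875), a difference of -0.0224, so each lay below its simulated range. Of the genes called for AngII against saline, 83.2% had the opposite sign with FI, against 72.4% in the simulations (70.2% to 75.0%), and 80.5% against 67.7% (65.8% to 69.9%) without AngII_FI 3. The simulations drew counts around the means fitted to these libraries. With all 12 libraries, every simulated library took a spread fitted with AngII_FI 3 included (common biological coefficient of variation 0.343, against 0.269 without it). AngII_FI 3 thus added spread to the simulated AngII libraries, so an observed r or covariance above that range does not decide about FI. The simulations called more genes for AngII against saline, on average 689 against the observed 388, and 1340 against 683 without AngII_FI 3. The observed and simulated shares thus cover different sets of genes, and the gap between them does not decide whether FI reversed changes. With the AngII libraries split between the comparisons, r ranged from -0.10 to 0.06 over the 6 assignments. By edgeR 0 genes were called higher with angiotensin II and lower with FI and 0 in the opposite order, while DESeq2 gave 19 and 3. The simulations gave 0 genes called in opposite directions with all 12 libraries and 0 to 1 without AngII_FI 3.

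**Figure D3:**
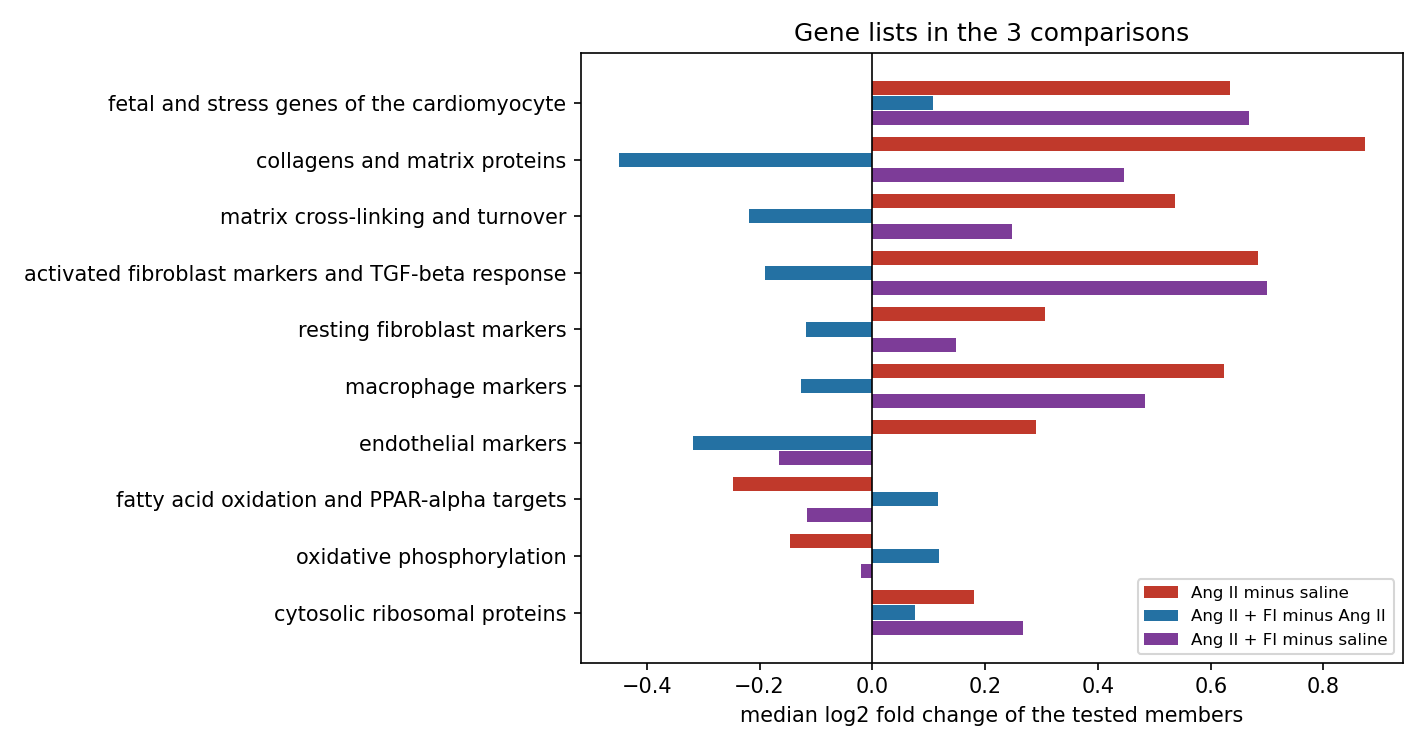
Median log2 fold change of the tested members of 10 gene lists (bars, from 0) in the 3 comparisons. The collagen bar is at 0.87 for AngII minus saline, -0.45 for AngII_FI minus AngII and 0.45 for AngII_FI minus saline, and the bar of the fetal and stress genes is at 0.63, 0.11 and 0.67.

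The comparison of AngII_FI with saline asks what still differs from saline when FI is given. Part of the stress genes of the cardiomyocyte and of the matrix genes were higher. Nppb went from 101 ± 26.4 to 491 ± 68.9 CPM, a log2 fold change of 2.27 ± 0.23 (SE, n = 4 per group, edgeR adjusted p = 0.00129), and Nppa rose by 1.73 ± 0.13 and Acta1 by 1.77 ± 0.32. Of 14 fetal and stress genes 5 rose. Of 31 collagens and matrix proteins 7 rose (19 adjusted over the list alone), with a median of 0.45; Ltbp2 rose by 1.70 ± 0.21, Col8a1 by 1.20 ± 0.16 and Col1a1 by 0.49 ± 0.10, while Col3a1 was at 0.25 ± 0.16 and did not pass. The adjusted p of the collagen list was 0.182 with an estimated correlation and 0.00346 by fry. Ccn2 rose by 1.31 ± 0.11, Cilp by 1.36 ± 0.15 and Postn by 1.11 ± 0.16, among the 8 that rose of 23 activated fibroblast markers. The mean log2 CPM differed by 0.51 for macrophage markers (exact two-sided permutation p = 0.0286, adjusted p = 0.0482), 0.19 for resting fibroblast markers (p = 0.229), 0.0342 for pericyte and smooth muscle markers (p = 0.857) and -0.0773 for endothelial markers (p = 0.686). Without AngII_FI 3 the last 2 were -0.0832 (exact two-sided permutation p = 0.400) and -0.00614 (p = 1.0). Acta1 lost its call in 6 (1.57 to 2.09) and Col1a1 in 10 (0.44 to 0.58).

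The macrophage markers C1qc and C1qa rose by 0.60 ± 0.10 and 0.55 ± 0.10, and Ddit3, a transcription factor of the integrated stress response whose model overlaps another, by 0.73 ± 0.12. The adjusted p with an estimated correlation was 0.194 for macrophage markers and 0.314 for the unfolded protein and integrated stress response list. By fry these were 0.00767 and 0.0600. Il1b (0.40 ± 0.28), Il6 (1.90 ± 0.98), Tnf (-1.04 ± 0.60), Ccl2 (0.14 ± 0.41), Nlrp3 (-0.72 ± 0.66), Tgfb1 (0.32 ± 0.14), Agtr1a (-0.36 ± 0.18), Nqo1 (0.14 ± 0.11), Hmox1 (0.77 ± 0.17), Myh7 (0.45 ± 0.21), Myh6 (0.15 ± 0.17) and Atp2a2 (-0.29 ± 0.12) did not pass. Il6 averaged under 1 CPM in both groups, so its value rests on few counts. Among called protein-coding genes with a mean of at least 1 CPM and no overlap between the groups, the largest increases included those of Tceal7 (4.37 ± 0.80), Wnt9b (2.34 ± 0.43), Nppb, Edn3 (2.27 ± 0.34), Mybpc2 (2.18 ± 0.19), Tnfrsf12a (2.04 ± 0.32), Pthlh (1.92 ± 0.38), Inhba (1.77 ± 0.28) and Acta1. The largest decreases among the same genes were those of Gm11992 (-2.31 ± 0.45), Fam222a (-1.45 ± 0.22), Stum (-1.41 ± 0.25), Foxo6 (-1.32 ± 0.27), Zfp41 (-1.26 ± 0.26), Ky (-1.18 ± 0.20), Tet1 (-1.17 ± 0.23), Gal3st2c (-1.15 ± 0.19), Plxnb3 (-1.09 ± 0.22) and Bcl6 (-1.09 ± 0.22). C1qc lost its call in 5 (0.56 to 0.66), C1qa in 7 (0.46 to 0.60) and Ddit3 in 6 (0.69 to 0.76). Tceal7 lost its call in 8 (3.89 to 5.36), Wnt9b in 6 (2.14 to 2.58) and Edn3 in 2 (without saline 2 and saline 4, 2.02 to 2.41). Tnfrsf12a lost its call in 1 (without saline 2, 1.84 to 2.25), Pthlh in 10 (1.77 to 2.35) and Inhba in 2 (without saline 1 and saline 2, 1.52 to 1.95). Acta1 lost its call in 6 (1.57 to 2.09), Gm11992 in 9 (-2.64 to -2.17) and Stum in 6 (-1.62 to -1.26). Foxo6 lost its call in 9 (-1.53 to -1.24), Zfp41 in 10 (-1.43 to -1.18) and Ky in 5 (-1.32 to -1.08). Tet1 lost its call in 11 (-1.29 to -1.06), Gal3st2c in 4 (-1.22 to -1.10) and Plxnb3 in 9 (-1.21 to -1.001). Bcl6 lost its call in 10 (-1.20 to -0.92). One AngII_FI library lay far from the others of its group for Bcl6, Foxo6 and Tnfrsf12a.

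In all, 125 genes were higher and 45 lower in AngII_FI than in saline by edgeR. Of these, 98 higher and 19 lower were also called in AngII against saline, where independent lists would share 1.96 and 0.298, and 0 were called in opposite directions. The saline libraries enter both comparisons, so independent lists are not the value without an effect. Over 25 simulations of AngII and AngII_FI groups that did not differ from saline, 0 genes were shared in either direction with all 12 libraries. Every simulated library was drawn with a spread fitted with AngII_FI 3 included. These simulations called 0 genes for AngII and 0 to 1 for AngII_FI against saline. No gene could thus be shared, and their shared counts do not test the overlap. Across genes, the covariance of the log2 fold changes was 0.231 against a simulated 0.0940 (range 0.0855 to 0.107), and r was 0.512 against 0.4998 (0.471 to 0.537). Without AngII_FI 3 the covariance was 0.231 against 0.0919 (0.0795 to 0.103), and r was 0.575 against 0.448 (0.414 to 0.484). Then 135 higher and 28 lower genes were shared, against 0 to 1 and 0 in simulations that called only 0 to 1 genes in each comparison. With the saline libraries split 2 and 2 between the comparisons, 5 to 12 higher and 0 lower genes were shared over the 6 assignments, and the covariance was 0.1495 to 0.191. These splits called only 19 to 222 genes higher for AngII and 6 to 37 for AngII_FI, where independent lists would share 0.00898 to 0.179. Lower genes numbered 0 to 67 and 1 to 3, so few could be shared. Shared higher and lower genes numbered 31 and 1 without saline 1, 29 and 4 without saline 2, 55 and 6 without saline 3, 22 and 1 without saline 4, 30 and 5 without AngII 2, 42 and 5 without AngII 3, 31 and 3 without AngII 4, 32 and 4 without AngII_FI 1, 69 and 37 without AngII_FI 2 and 33 and 2 without AngII_FI 4. By camera 13 lists were higher and 2 lower (4 lower without saline 3 and 5 without AngII_FI 4), and 6 of the 35 splits called as many. Of these lists the activated fibroblast markers and the fetal and stress genes held with an estimated correlation (adjusted p = 0.0492 and 0.0492). Of all 41 lists, fry called 9. The counts moved with single libraries. Higher and lower genes numbered 43 and 5 without saline 1, 37 and 8 without saline 2, 67 and 9 without saline 3, 37 and 8 without saline 4, 57 and 18 without AngII 2, 80 and 26 without AngII 3, 71 and 21 without AngII 4, 35 and 9 without AngII_FI 1 and 35 and 6 without AngII_FI 4, and 165 and 55 without AngII_FI 3.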

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

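The tests of the liver transcripts' origin, of a response to FI, of the collagen median without AngII_FI 3 and of a lower share of all cells other than cardiomyocytes were chosen only after the result was seen. Of 435 groups of 4 libraries examined for a library far from the rest, 33 had a library whose gap to the nearest other exceeded Dixon's critical share of the group's range, where chance, at about 1 in 20 groups, gives 21.8. In AngII_FI the number of genes with at least 10 counts (gap 0.894 of the range) and the hepatocyte markers (0.9999) had such a library, as did the hepatocyte markers in AngII (0.890). In saline the genes were Cbr2 (0.837), Col12a1 (0.834), Hsp90aa1 (0.838), Kdr (0.844), Mybpc2 (0.834), Pthlh (0.856). In AngII they were Atf4 (0.863), Col8a1 (0.837), Cygb (0.870), Edn3 (0.868), Eln (0.840), Fabp4 (0.969), Flt1 (0.868), Hbb-bs (0.878), Loxl2 (0.927), Mmp2 (0.942), Mt2 (0.951), Pthlh (0.859). In AngII_FI they were Bcl6 (0.864), Etfbl (1.00), F13a1 (0.857), Foxo6 (0.852), Gdf15 (0.964), Gm19410 (0.893), Gsta3 (0.982), Gstm1 (0.907), Hspb1 (0.843), Snai3 (0.856), Tnfrsf12a (0.852), Trp53inp1 (0.974).

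AngII_FI 3 held hepatocyte transcripts. Wholly foreign tissue is argued against, since the contractile genes summed to 0.921 times the mean of the other AngII_FI libraries. A response of the heart to FI is argued against as well, since the highest hepatocyte sum among the others of the group was 38.1 CPM, below the 39.1 CPM of the highest saline library. RNA from a female liver may have entered this library, since Xist reached 12419 counts beside Y-linked genes near their usual level. How it entered was not tested.

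Over the 11 libraries without AngII_FI 3, 98 genes with a mean of at least 1 CPM differed 20-fold or more between libraries. Of them, 10.2% separated any 2 groups (95% Clopper-Pearson interval 5.00% to 18.0%). Of all tested genes, 13.5% did so for AngII against saline, 5.40% for AngII_FI against AngII and 9.31% for AngII_FI against saline. Separation is thus rare among all genes too, and the share in the set does not decide on a difference between the groups. Reads assigned now to one and now to another overlapping gene model may account for part of them, since 51, or 52.0%, overlap another gene on the same strand, against 8.57% of other genes (odds ratio 11.6, Fisher's exact two-sided p = 3.66e-28), and 44 of the 51 fell below 20-fold with overlapping models summed. For the overlapping genes that stayed at 20-fold or more, and for those without such overlap, Tceal7 and Zbtb42 among them, no other explanation was tested. The 20-fold range was taken across all groups, so a large difference between groups also brings a gene into the set. Tceal7 had 0 to 14 counts in saline, 100 to 143 in AngII and 70 to 200 in AngII_FI, so its range lay between saline and the groups with angiotensin II.

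Collagens and matrix proteins were lower with FI on balance, a call lost with an estimated correlation (adjusted p = 0.289) and by fry (adjusted p = 0.0554). Liver RNA is argued against, since the median was -0.42 without AngII_FI 3. The collagen score minus the resting fibroblast score also separated the groups (exact two-sided permutation p = 0.0286). The nearest values were close, -0.496 in AngII_FI 3 and -0.487 in AngII 3, and the difference was -0.32 without AngII_FI 3. This argues against a lower share of resting fibroblasts alone only if their markers come from those cells alone, which was not tested. Markers of activated fibroblasts were not subtracted, so a lower share of those cells stays open. Of the 35 splits of the 8 libraries, 1, the real one, gave a median as far from 0 as -0.45. The highest other was 0.32 in size. This argues against a chance split for the median, but 1 of 35 is the smallest share these splits can give. The collagen list also had the smallest camera p of the lists in this comparison, and the share was not adjusted for that choice. Chance is thus not excluded. A lower share of all cells other than cardiomyocytes stays open, since the collagen score minus the endothelial score did not separate the groups (-0.0897, exact two-sided permutation p = 0.514, and -0.19 with p = 0.0857 without AngII_FI 3). An effect of FI on matrix transcripts may also account for the pattern, as a hypothesis that these libraries do not separate from a change in cell shares.

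The number of genes called exceeded that of every other split for AngII against saline (388, highest other 2, 1 of 35) and for AngII_FI against saline (170, highest other 1, 1 of 35). This argues against chance, but 1 of 35 is the smallest share these splits can give, so chance is not excluded. Single libraries moved these counts, at the lowest to 79 higher and 11 lower without saline 4 and to 35 and 6 without AngII_FI 4, and the splits were not repeated without them. For AngII_FI against AngII the real split called 0 genes and the highest other 1; any split calls at least 0, so the 35 of 35 that did decide nothing about chance. Counts of lists differ from counts of genes: 3 of 35 splits called as many lists as the 24 for AngII against saline (highest other 25) and 6 of 35 as many as the 15 for AngII_FI against saline (highest other 25), so chance is not excluded there. For AngII_FI against AngII, 1 of 35 splits, the real one, called 19 lists by camera with the preset correlation, and the highest other 15. This argues against chance for that count, again at the smallest share possible, and does not exclude it. The count is for all 8 libraries together, and sets without 1 library were not split. Lists numbered 4 higher and 8 lower without AngII 1, 4 and 10 without AngII 2, 5 and 8 without AngII_FI 2 and 5 and 9 without AngII_FI 4. Without AngII_FI 3 the macrophage, resting fibroblast, NADPH oxidase, NRF2 and unfolded protein lists lost their calls (camera adjusted p = 0.507, 0.206, 0.246, 0.206 and 0.317). The type I interferon, immediate early gene and glucocorticoid lists were then called (0.0194, 0.0222 and 0.0450). With an estimated correlation (smallest adjusted p = 0.289) or by fry (smallest adjusted p = 0.0554) 0 lists were called there.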

How the results depend on the processing

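Leaving out both libraries with hepatocyte transcripts (AngII_FI 3 and AngII 3), summing overlapping models, leaving out mitochondrial genes and splitting the saline libraries were chosen after the data were seen. The cause was not tested for any change below except where fewer libraries or genes enter by construction. Higher and lower genes were 666 and 433 for AngII against saline, 12 and 30 for AngII_FI against AngII, 486 and 361 for AngII_FI against saline by DESeq2, and DESeq2 gave 19 genes higher with angiotensin II and lower with FI and 3 in the opposite order. They were 152 and 38 for AngII against saline, 50 and 14 for AngII_FI against saline with no filter, 68 and 14 for AngII against saline, 42 and 14 for AngII_FI against saline at an absolute log2 fold change of at least 1, and 358 and 208 for AngII against saline, 35 and 13 for AngII_FI against saline with only the groups compared. A filter at 1 CPM gave 185 and 82 lower genes in these comparisons, and upper-quartile scaling 73 higher in AngII_FI against saline. Without both libraries with hepatocyte transcripts AngII against saline had 66 lower genes and AngII_FI against AngII 2 lower. With loci summed and AngII_FI 3 left out, higher and lower genes were 457 and 255 for AngII against saline, 0 and 1 for AngII_FI against AngII, 189 and 66 for AngII_FI against saline. Genes called higher and lower in both comparisons with saline were 284 and 178 by DESeq2, 88 and 32 by limma-voom, 39 and 8 with no filter, 29 and 6 with only the groups compared and 33 and 6 with the replicate number as a block.

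With 1 library left out, higher genes ranged from 79 to 441 and lower from 11 to 242 for AngII against saline, from 0 to 1 in both directions for AngII_FI against AngII, and from 35 to 165 and 5 to 60 for AngII_FI against saline. The opposite-direction overlaps ranged from 0 to 1 in each order. The correlation ranged from -0.35 to -0.0557, was -0.42 without both libraries with hepatocyte transcripts and -0.34 with loci summed and AngII_FI 3 left out. With AngII libraries 1 and 2, 1 and 3, 1 and 4, 2 and 3, 2 and 4, or 3 and 4 in the first comparison and the others in the second it was -0.10, 0.0039, -0.0628, 0.0185, -0.0277 and 0.0568. Lists called higher and lower by camera with an estimated correlation were 5 and 0, 0 and 0, and 2 and 0 in the order above; fry called 13 and 2, 0 and 0, and 9 and 0. With 1 library left out, lists higher in AngII_FI against AngII ranged from 4 to 10 and lower in AngII_FI against saline from 2 to 5.

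The replicate numbers did not clearly pair the libraries. Deviations from the group means correlated at -0.0572 to 0.105 for libraries with the same number and at -0.0795 to 0.0790 for different numbers. The 0.105 was between AngII_FI 3 and AngII 3, the 2 libraries with hepatocyte transcripts. In the 3 comparisons 2, 2 and 0 of 4 libraries correlated best with their own number. With the number as a block, higher and lower genes were 105 and 19 for AngII against saline, 51 and 10 for AngII_FI against saline, and the correlation was -0.32.

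Of the named genes' log2 fold changes, those that changed sign follow, with ranges over the fits with 1 library left out. Etfbl in AngII against saline (-0.20 with loci summed, -0.20 with loci summed and AngII_FI 3 left out) and Ccl2 in AngII against saline (-0.27 without saline 4, range -0.27 to 0.36) changed sign. Myh6 in AngII against saline (0.00866 without saline 4, range -0.31 to 0.00866) and Myh7 in AngII against saline (-0.0213 without saline 2, range -0.0213 to 0.32) changed sign. Nqo1 in AngII against saline (-0.0128 without saline 3, -0.0626 without AngII 4, range -0.0626 to 0.11) and Tnf in AngII against saline (0.00912 without saline 3, range -0.65 to 0.00912) changed sign. Vtn in AngII_FI against AngII (-0.22 without AngII_FI 3, -0.27 without both libraries with hepatocyte transcripts, -0.22 with loci summed and AngII_FI 3 left out, range -0.22 to 2.76) and Trp53inp1 in AngII_FI against AngII (-0.0384 without AngII_FI 3, -0.12 without both libraries with hepatocyte transcripts, -0.0389 with loci summed and AngII_FI 3 left out, range -0.0384 to 2.26) changed sign. Gdf15 in AngII_FI against AngII (-0.65 without AngII_FI 3, -0.63 without both libraries with hepatocyte transcripts, -0.65 with loci summed and AngII_FI 3 left out, range -0.65 to 2.77) and Acta1 in AngII_FI against AngII (-0.00409 without AngII 1, -0.0129 without AngII_FI 4, range -0.0129 to 0.22) changed sign. Agtr1a in AngII_FI against AngII (-0.0675 without both libraries with hepatocyte transcripts) and Ccl2 in AngII_FI against AngII (-0.0562 without AngII_FI 1, range -0.0562 to 0.18) changed sign. Ccl2 in AngII_FI against saline (-0.19 without saline 4, range -0.19 to 0.45) changed sign. Among fits with 1 library left out, 3315 named-gene values stayed on their side of the threshold with their sign, 420 lost and 32 gained the threshold and 13 changed sign; DESeq2 kept 224 and gained 82. At these depths and group sizes, 9.38% and 16.7% of 1.5-fold changes were recovered in simulation for AngII against saline and AngII_FI against AngII.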

Other observations

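Lymphocyte markers had medians of 0.00, 0.01 and 0.08 on the log2 scale for AngII against saline, AngII_FI against AngII and AngII_FI against saline, and mitochondrially encoded mRNAs of 0.05, -0.04 and 0.01. Renin-angiotensin genes had medians of -0.38, 0.12 and -0.31, with means of -0.20, 0.36 and 0.16, and none of these lists passed camera's test. Without AngII_FI 3 the medians for AngII_FI against AngII and against saline were -0.0616 and -0.0899 for lymphocyte markers, 0.0602 and 0.11 for mitochondrially encoded mRNAs and -0.0782 and -0.37 for renin-angiotensin genes. Cytosolic ribosomal proteins were higher in both groups with angiotensin II than in saline by camera, with medians of 0.18 and 0.27, but not with an estimated correlation (adjusted p = 0.360 and 0.314). By fry the adjusted p was 0.0660 for AngII and 0.0237 for AngII_FI. Rpl3, which overlaps another model, was at 0.48 ± 0.08 and 0.60 ± 0.08.

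Among the library measures, the total count, the genes with at least 10 counts, the share of the 10 highest genes, the mitochondrial share and the hepatocyte sum gave 15 exact two-sided permutation tests between groups, with a smallest p of 0.0857 and adjusted p of 0.75 and above. AngII 3 held 95.6 CPM of hepatocyte markers.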
